A study of Bos taurus with 6 samples.

How the data were processed

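Liver biopsies were taken from Angus × Simmental cattle, 3 given rumen-protected niacin and 3 controls. Niacin (vitamin B3) is a precursor of the coenzyme NAD, and rumen protection is a coating meant to carry it past the rumen microbes. Per the labels' protocols, both groups had free access to Bermudagrass hay. Each animal also received a daily supplement of fescue seed free of endophyte (1.61 kg), molasses (0.1 kg) and a corn and soybean pellet (1.61 kg). Corn and soybean meal each formed 46.5% of the pellet, with soybean oil at 2% and wheat middlings at 5%. The niacin dose and the length of supplementation are not given in the sources used here. Libraries were poly(A)-selected, strand-specific and made from 1500 ng of total RNA, and were sequenced as 150-bp paired-end reads, per the labels' protocols.

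The deposited values are raw counts per Ensembl gene, whole numbers with a different total in every library, for 23833 gene identifiers in 6 libraries. Per the submitters' processing notes, FastQC 11.5, Trimmomatic 0.36, TopHat2 2.1.1, Cufflinks 2.2.1, bedtools 2.30.0, HTSeq and DESeq2 were used, with no role or order stated. The genome build, the annotation release and the strand setting of the counting are not given in the sources used here. Replicates were deposited as separate columns, each named exactly as 1 sample's description, and 0 columns lacked a sample. Values of reads without molecular identifiers are not independent molecules, so counting intervals would cover counting error only. Among counts from 1 to 50, between 54.8% and 59.7% were even numbers, with exact (Clopper-Pearson) 95% intervals that lay above an equal split in each of the 6 libraries (lowest bound 53.6%).

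The deposited table gives Ensembl identifiers without gene symbols. The RefSeq gene table used here (assembly ARS-UCD2.0, 37063 genes) carried an Ensembl identifier for 0 genes, so 0 identifiers could be paired with a symbol. No gene is therefore named, no coordinates are given, and GC content and gene length were not checked. The 36 gene lists written before the data were examined (niacin and NAD metabolism, liver metabolism, stress and immune programmes, and markers of other cell types that a biopsy can hold) could not be applied, and neither could the parts of the rule for named genes that need a symbol. What remained of that rule was the genes with the smallest p in each direction. Identifiers are printed for 1 gene higher in niacin and 2 genes lower in niacin under that rule, and for 1 further gene, the most abundant of those higher in niacin, which was chosen after its values were seen.

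Groups came from the agent label. The labels give each library its own animal code but no numbers shared between groups, so replicate numbers only name libraries. The labels do not say in words that the codes are separate animals, and p-values measure the spread between these samples. Counts per pair of libraries differed by 266 to 1250 times the sampling variance per gene (mean chi-square over genes with at least 20 counts in the pair), so no library was a second deposit of another.

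Genes were filtered with filterByExpr (minimum count 10), libraries were scaled with TMM, and the groups were compared with edgeR's quasi-likelihood F test (edgeR 4.0.16, R 4.3.3, robust dispersion, no covariate), with Benjamini-Hochberg adjustment over all genes tested and a threshold of 0.05. Folds are niacin over control. The standard error of a log2 fold is the fold divided by the square root of its F statistic. CPM values are TMM-scaled counts computed here per 1e+06 counts of a library, and shares of counts use the raw totals. Principal components were computed on log2 CPM with a prior count of 2. Single values per library were compared with a two-sided exact permutation test, which cannot go below p = 0.1 with 3 libraries against 3.

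The test was run on simulated data: counts drawn from the real means, dispersions and library sizes, with 100 genes changed 2-fold and 100 changed 4-fold. Among 14485 genes tested in that simulation of the niacin and control comparison, 8 of the 100 genes changed 2-fold and 65 of the 100 genes changed 4-fold were recovered, and 7 of 14285 unchanged genes were called. The changed genes were drawn from those with a mean of at least 1 CPM. They were far fewer than the 2622 genes called in the real comparison, which makes the adjusted threshold stricter. The simulation thus missed most 2-fold changes, and its recovery may understate that of the real comparison.

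The comparison was repeated with DESeq2 1.42.0, limma-voom (limma 3.58.1), RLE and upper quartile factors, no filter or a filter of 1 CPM in 3 libraries, non-robust dispersion, other thresholds, removal of the 20 most abundant genes, each library left out in turn, and a term for the last letter (M or F) of the code in the description. That letter splits 2 to 1 in each group and its meaning is not stated. Alternatives chosen after seeing the data were library totals without a TMM factor, TMM computed on genes of at least 100 CPM, thinning every library to the smallest total, halving every count, and scaling each niacin library for the share of counts that the higher genes added.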

Results

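Gene expression in liver biopsies was measured by RNA sequencing in 3 cattle given rumen-protected niacin and 3 control cattle on the same basal diet. The question was how niacin supplementation changed hepatic gene expression. The niacin libraries held 54478409, 111478194 and 91216378 counts, and the control libraries 57315443, 48593701 and 48670988 counts. Mean totals were 85724327 ± 28894045 counts (SD, n = 3) with niacin and 51526711 ± 5013338 counts (SD, n = 3) in controls, a difference that did not pass the exact permutation test (p = 0.2). No count was recorded in any library for 3572 of the 23833 genes, and 14839 genes had enough counts to be tested.

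Liver expression profiles separated by group. The first principal component held 57.1% of the variance and placed the 3 niacin libraries between 48.8 and 97.8 and the 3 control libraries between -85.2 and -74.9. Niacin replicate 3 lay closest to the controls. The second component held 16% and set control replicate 2 (-76.7) apart from the other controls (33.9 and 35.6). Spearman correlations of counts across genes were 0.959 to 0.965 between niacin libraries, 0.953 to 0.963 between control libraries and 0.929 to 0.953 between libraries of different groups.

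**Figure D1:**
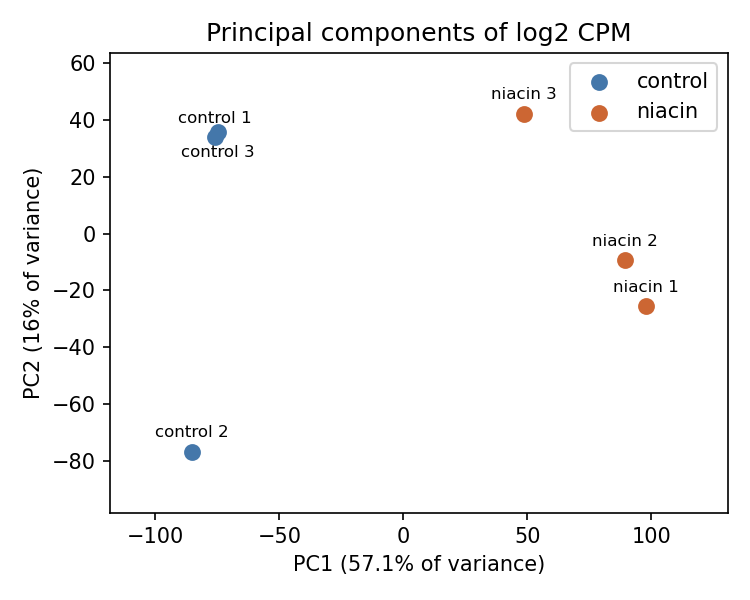
Principal components of log2 CPM over the 14839 tested genes, with 1 point per library, the first component (57.1% of variance) on the x axis and the second (16%) on the y axis. The niacin libraries all lie at 48.8 or above on the first component and the control libraries at -74.9 or below.

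With niacin, 2109 genes were higher and 513 were lower than in control liver at an adjusted p under 0.05, 2622 of 14839 genes tested (edgeR quasi-likelihood test with Benjamini-Hochberg adjustment, n = 3 per group). Higher genes made up 80.4% of the calls. Higher genes also had the larger changes, with a median log2 fold of 2.2 (quartiles 1.55 and 3.29) against -1.24 (quartiles -1.53 and -1.08) for lower genes. More than 4-fold changes were seen for 1199 of the higher genes and 53 of the lower genes, and 323 genes were over 16-fold higher. The niacin and control libraries did not overlap for 2070 of the 2109 higher genes and 496 of the 513 lower genes. Over all tested genes, the groups did not overlap for 34.4%. Chance gives 10% for 3 against 3 as an average over splits, but genes vary together, so 1 split can lie far from it. The number of lower genes was less firm than that of higher genes. It was 171 without niacin replicate 1, 1157 without niacin replicate 3, 283 without control replicate 1, 209 without control replicate 2 and 286 without control replicate 3, while the total fell to 1653 without niacin replicate 1. With upper quartile factors in place of TMM, which moved the median log2 fold of all tested genes from 0.07 to -0.07, 69.6% of the calls were higher. With TMM computed on genes of at least 100 CPM, chosen after seeing the data, 90.2% were higher and 264 genes were lower.

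**Figure D2:**
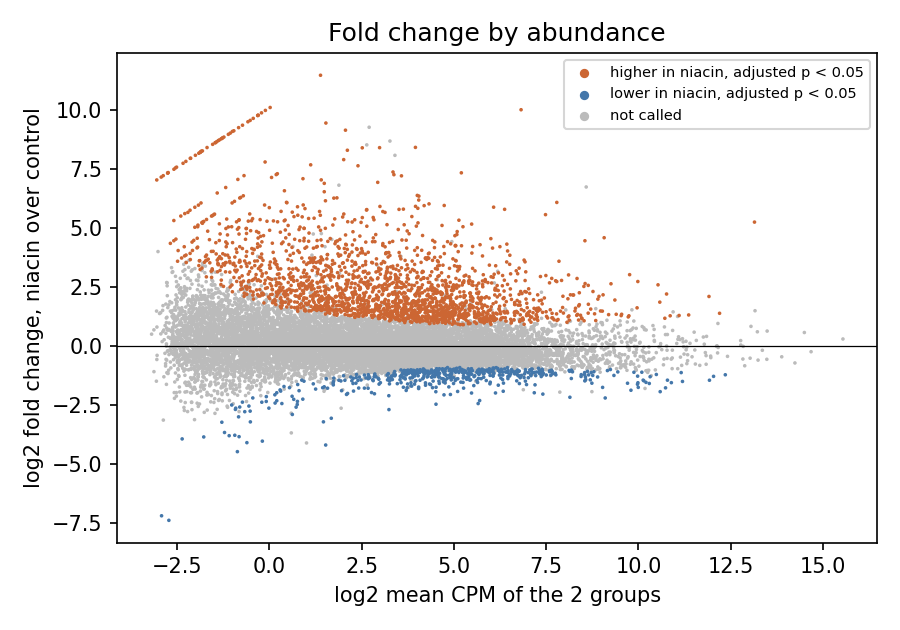
Log2 fold change of niacin over control for each of the 14839 tested genes (y axis) against the log2 of its mean CPM (x axis), with genes higher in niacin in orange, genes lower in blue and genes not called in grey. Orange points (2109) outnumber blue points (513) and reach larger changes. The fitted folds of genes with no count in 1 group, which form the upper left diagonal, depend on the prior count.

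The balance between higher and lower genes shifted with abundance. Among 3043 tested genes with a mean under 1 CPM, 273 were higher and 27 lower. From 1 to 10 CPM, 821 of 5303 genes were higher and 84 lower. From 10 to 100 CPM, 858 of 5266 genes were higher and 292 lower. From 100 to 1000 CPM, 146 of 1084 genes were higher and 90 lower. Of the 143 genes at 1000 CPM or more, 11 were higher and 20 lower. Higher genes were thus 91% of the calls in the lowest abundance class and 35.5% in the highest. The median log2 fold of all tested genes went from 0.35 in the lowest class to -0.25 in the highest. Only 1 of the 20 most abundant genes was called, and it was higher with niacin.

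Genes called higher took up 18%, 17.1% and 10.9% of all counts in niacin replicates 1, 2 and 3, and 3.64%, 4.45% and 4.05% in control replicates 1, 2 and 3. The means were 15.3% ± 3.84 (SD, n = 3) with niacin and 4.05% ± 0.404 (SD, n = 3) in controls. Genes called lower took up 4.01% ± 0.248 (SD, n = 3) with niacin and 10.1% ± 1.47 (SD, n = 3) in controls. Neither share overlapped between the groups, and each exact permutation p was 0.1, the smallest that 3 libraries against 3 allow. The genes were called on these same libraries, so the shares describe the size of the change and are not independent evidence of it. The 323 genes over 16-fold higher took up 3%, 2.87% and 1.4% of counts in niacin replicates 1, 2 and 3, and 0.0412%, 0.115% and 0.0535% in control replicates 1, 2 and 3.

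**Figure D3:**
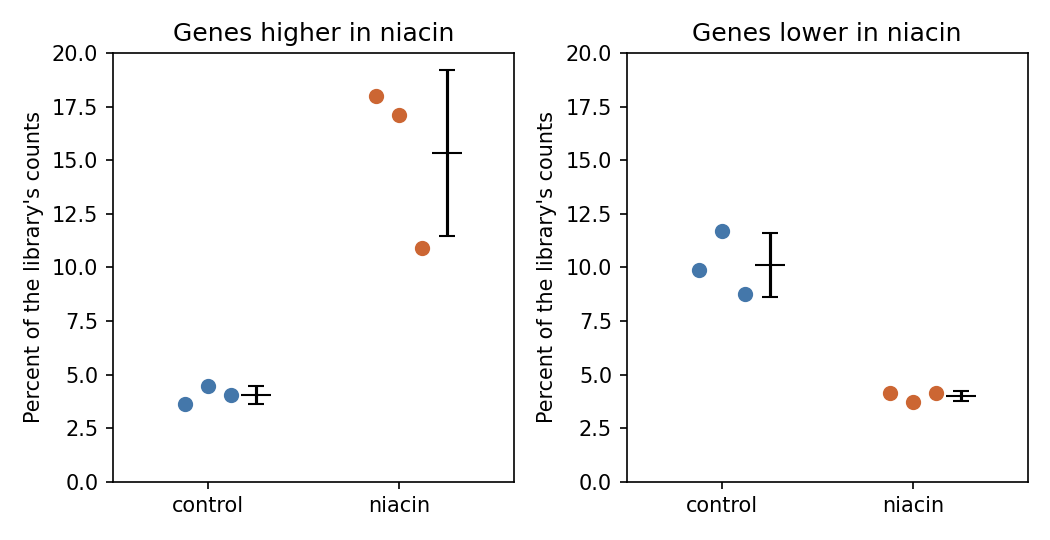
Percent of each library's counts (y axis) in the genes called higher (left) and lower (right) in niacin, with 1 point per library and a dash and bar for the mean and SD of the 3 libraries in each group. The higher genes hold 10.9% to 18% of niacin counts and 3.64% to 4.45% of control counts.

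Expression of 47 higher genes was detected only with niacin at this depth: they had 0 counts in all 3 control libraries. They were all of the tested genes with no control count. The filter kept such a gene only where all 3 niacin libraries passed its cutoff, so that all 47 were called higher was largely set by the filter. Counts over the 3 niacin libraries together, not mean CPM, were set against a floor of 3 counts over the 3 control libraries together (0.0193 CPM). By that measure these genes were at least 12.1-fold to at least 277-fold higher, with a median bound of 36-fold. These bounds take each count as independent and leave out the spread between libraries. They would be lower if both mates of a read pair were counted. With those genes at their bound instead of their fitted fold, 316 genes were over 16-fold higher and the median log2 fold of the higher genes was 2.2. In the other direction, 2 lower genes had 0 counts in all 3 niacin libraries.

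The most abundant gene that rose was ENSBTAG00000010123, singled out after its values were seen. It took up 2.08%, 2.16% and 0.976% of all counts in niacin replicates 1, 2 and 3, and 0.0214%, 0.0865% and 0.029% in control replicates 1, 2 and 3, and ranked 12 by mean share over the 6 libraries. Its level was 17649 ± 7084 CPM (SD, n = 3) with niacin and 461 ± 379 CPM (SD, n = 3) in controls, a log2 fold of 5.26 ± 0.61 (SE) with an edgeR adjusted p of 2.94e-05. Over the alternatives that tested it, that log2 fold ran from 4.97 to 6.18, and was highest without control replicate 2. The gene with the smallest p was ENSBTAG00000002178, at 73.0 ± 35.6 CPM (SD, n = 3) with niacin and 0.446 ± 0.103 CPM (SD, n = 3) in controls. Its log2 fold was 7.34 ± 0.49 (SE), with an edgeR adjusted p of 4.04e-07.

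Among lower genes, ENSBTAG00000011830 had the smallest p. It fell from 5.45 ± 3.94 CPM (SD, n = 3) in controls to 0.297 ± 0.0447 CPM (SD, n = 3) with niacin, a log2 fold of -4.18 ± 0.62 (SE) with an edgeR adjusted p of 0.000143. Its control level varied from 1.73 CPM in replicate 1 to 9.58 CPM in replicate 2. Over the alternatives its log2 fold ran from -4.58 to -3.50, and was weakest without control replicate 2. The next was ENSBTAG00000002693, which fell from 36.0 ± 1.30 CPM (SD, n = 3) to 9.49 ± 1.03 CPM (SD, n = 3), a log2 fold of -1.92 ± 0.31 (SE) with an edgeR adjusted p of 0.000335. The files pair none of these identifiers with a gene symbol, so the genes are given by identifier alone.

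More genes were detected with niacin. At least 1 count was found for 17942 ± 337 genes (SD, n = 3) with niacin and 16796 ± 818 genes (SD, n = 3) in controls. After every library was thinned to the smallest total, the numbers were 17674 ± 192 and 16759 ± 800 (SD, n = 3 each), without overlap between the groups and with an exact permutation p of 0.1, the smallest the design allows. The gap between the groups was narrow, from 17423 genes in control replicate 3 to 17517 in niacin replicate 1. Control replicate 2, at 15871, stood apart from the other controls (16982 and 17423) and lowered their mean. The 20 most abundant genes took up 26.9% ± 1.69 of counts with niacin and 25.1% ± 2.14 in controls (SD, n = 3 each, exact permutation p = 0.3).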

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

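Across 22 alternatives, each of the 3 gene counts (all calls, higher and lower) was recomputed, and 55 of 66 values stayed within 1.5 times of the main counts of 2622, 2109 and 513. Values that moved further concerned lower genes, apart from the total without niacin replicate 1. Lower genes numbered 943 with DESeq2 and 820 with upper quartile factors. They numbered 902 at an adjusted p under 0.10 and 264 with TMM computed on genes of at least 100 CPM, a choice made after seeing the data that moved the median log2 fold of all tested genes from 0.07 to 0.23. Scaling each niacin library for the share of counts that the higher genes added, also chosen after seeing the data, left 264 lower genes and a median of 0.24. All 264 were in each case among the 513, and 513 of the 943 DESeq2 calls were. With each library left out in turn, all calls ranged from 1653 (without niacin replicate 1) to 3549 (without niacin replicate 3), higher genes from 1436 to 2392 and lower genes from 171 to 1157. Between these ends, lower genes were 283, 209 and 286 without control replicates 1, 2 and 3. Leaving out niacin replicate 3, the library nearest to the controls, gave the most calls, and 2451 of the 2622 genes were among them. For the remainder the cause was not tested. Counts with limma-voom were 1967 higher and 513 lower, and the code letter as a term gave 2222 higher and 533 lower. All 87 values of the 4 printed genes kept their direction and their side of the threshold, with edgeR, DESeq2 or limma adjusted p up to 0.00475. Tests of the 36 gene lists, planned before the data were examined, were not run because no identifier could be paired with a symbol. No paired analysis was possible because the labels give the groups no shared numbers. Making the depths equal moved the calls little, to 2612 with every library thinned to the smallest total. That total was the 48593701 counts of control replicate 2, which thus kept its full depth, and control replicate 3 (48670988 counts) nearly did. With every count halved and rounded, 2592 genes were called. Halving draws no new sample of reads and adds no sampling noise, so it does not test less depth. Depths under the smallest total were not tested. At the full depth of these libraries, the simulation, in which far fewer genes changed than were called here, recovered 8 of 100 changes of 2-fold.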

Other observations

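The tests of other splits, of the ratios between niacin libraries, of dilution, of thinned libraries and of halved counts, and 2 of the 4 other scalings (library totals alone and TMM on genes of at least 100 CPM), were chosen only after the main result was seen. The criteria for the 2 explanations of the ratios by fold class were set after those ratios were seen. RLE and upper quartile factors and the removal of the 20 most abundant genes were chosen before the data were examined.

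Tested genes with a higher mean with niacin, called or not, stood at different levels in the 3 niacin libraries, and the median ratio of replicate 3 to replicate 1 was similar in 3 classes of fold, while that of replicate 2 to replicate 1 fell with the fold. Among 1845 tested genes between 2 and 4-fold higher, the median log2 ratio of the excess over the control mean was -0.97 (95% bootstrap interval -1.03 to -0.92, 1657 genes with an excess in every niacin library). Among 1058 genes between 4 and 16-fold higher it was -0.99 (-1.03 to -0.94, 1039 genes), and among 336 genes over 16-fold higher it was -0.95 (-1.02 to -0.87, 329 genes). For niacin replicate 2 against replicate 1, the medians were -0.06 (-0.12 to -0.01), -0.19 (-0.27 to -0.12) and -0.30 (-0.40 to -0.24) in the same order. In CPM with 0.05 added, not as an excess, the median log2 ratio of replicate 3 over replicate 1 was -0.88 for 268 genes over 16-fold higher and 0.39 for 4890 genes that changed little (log2 fold within 0.5) in the same range of niacin CPM. These intervals are over genes, which are not independent replicates.

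One hypothesis is that the biopsies of the niacin animals held RNA of cells that the control biopsies largely lacked, at a lower share in replicate 3, and 1 source of the same make-up in each animal would give 1 excess ratio per pair of libraries in every fold class. From the 2 to 4-fold to the over 16-fold class the median changed by 0.02 for replicate 3 over replicate 1. For replicate 2 over replicate 1 it changed by -0.24, and the intervals did not overlap. In the second pair the SD over genes was 2.36 times that of little-changed genes (1.66 and 0.704), against 1.45 times in the first (1.29 and 0.884). Within 2-fold of the median of their set lay 74.6% of the over 16-fold genes and 87.5% of little-changed genes in the second pair. In the first pair these were 83.2% and 76.6%, the reverse of the order that the SD gave. The second pair thus argues against such a source, within the limits of how the genes were chosen. The first pair does not decide. Little-changed genes were themselves offset by a median log2 ratio of 0.39 in that pair, against 0.04 in the second. That offset was not removed before the excess was taken and would weigh most in the 2 to 4-fold class. The rival, a response to niacin whose log folds were scaled by 1 factor per animal, predicted from the 4 to 16-fold genes a gap of -1.32 (log2 CPM) between replicates 3 and 1 in the over 16-fold genes, where the median was -0.88 (-0.96 to -0.83), and a gap of -0.27 between replicates 2 and 1, where it was -0.28 (-0.35 to -0.21), so the first pair argues against it and the second goes with it. Choosing genes by a mean that 1 library can lift may add to the 2.36 and the -0.24. The need for an excess in every niacin library left out more genes of the 2 to 4-fold class, which may also affect the -0.24. Of the 1845 genes in that class, 891 were called, and replicate 2 was the only niacin library with the code letter F. Whether either affected the -0.24 was not tested. Sources whose make-up differed between animals and a response of another form stay open, and markers of other cells could not be looked up.

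The preponderance of higher genes may also be technical in origin, and 3 such explanations are argued against as its whole cause. After every library was thinned to the smallest total, 2612 genes were called and 79.7% of them were higher, against 2622 and 80.4% at full depth. The greater depth of niacin replicates 2 and 3 thus did not produce the preponderance. The 20 most abundant genes held 26.9% of counts with niacin and 25.1% in controls, so they could hardly have produced the preponderance. Without them, 81.6% of 2630 calls were higher, a result that these similar shares made likely in advance. Under the 4 other scalings run, higher genes were 76.3% (RLE), 69.6% (upper quartile), 79.7% (library totals) and 90.2% (TMM on genes of at least 100 CPM) of the calls, so the scaling moved the share and kept a majority. RNA from other cells and a response to niacin stay open. Technical causes other than these 3 were not tested and stay open too.

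A candidate explanation of the lower genes is dilution by the RNA behind the higher genes, which added 13.9%, 13.1% and 6.87% of counts to niacin replicates 1, 2 and 3 over the mean control share, 11.3% on average. That would shift every other gene by a log2 fold of about -0.17. With each niacin library scaled for its added share, which moved the median of all tested genes by 0.17, 264 of the 513 genes were still called lower, against a limit of 26 set as 5% of the 513. The 249 genes that were lost went from a median log2 fold of -1.08 to -0.90, with a median edgeR adjusted p of 0.074, so they ended near the threshold with most of their fold. The weakest of the lost genes stood at -0.90 before the scaling, far beyond a shift of -0.17. The limit of 26 was therefore likely to be passed whatever the cause. The scaling was also applied on top of the TMM factors, with which the median log2 fold of all tested genes was 0.07. The folds of the lower genes lay beyond the shift of -0.17, but a choice by adjusted p keeps mainly large folds whatever their cause. Neither the count that remained nor the folds thus decide whether dilution of this size was the whole cause of the lower genes. The added share covers only genes called higher, and a larger dilution was not tested. The 1195 genes with a control mean of at least 100 CPM had a median log2 fold of -0.33. A loss of other cells from the niacin biopsies, a response to niacin and other technical causes stay open, untested.

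The 6 libraries can be split into 3 and 3 in 10 ways. The split into niacin and control gave 2622 genes and the highest of the other 9 gave 1, so 1 of 10 splits reached the real count. With 10 splits, the design is too small for a share under 0.05.

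In a fit with the last letter of the description code as a term, 3 genes differed by the letter at an adjusted p under 0.05 (edgeR quasi-likelihood test). In the same fit, 2755 differed between niacin and control. Even numbers made up 56.4%, 59.7% and 54.8% of counts from 1 to 50 in control replicates 1, 2 and 3, and 57.9%, 57.9% and 56.4% in niacin replicates 1, 2 and 3. Counting both mates of a read pair could give such an excess, and with every count halved and rounded, 2592 genes were called.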
